A study of Xenopus laevis with 6 samples.

How the data were processed

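The series measured transcripts in Xenopus laevis ectodermal explants on 6 one-colour Affymetrix Xenopus laevis arrays, 1 per sample, from total RNA with a biotin label, per the labels' protocols. The authors deposited 1 table with an intensity per probe set and array on a linear scale. The method by which the authors summarised probes into that intensity, the background correction and the scaling between arrays are not given in the sources used here. The smallest deposited value per array lay between 0.8 and 1, and no detection call came with the values used. Array medians of intensity were 41.4 and 56.7 without Dex, 39.6 and 54.4 with Dex, and 36.6 and 58.0 with geminin and Dex, replicate 1 first, a range of 0.67 on the log2 scale.

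Groups and replicate numbers were taken from the sample titles and characteristics, and gave 3 groups of 2. Groups, tests, gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where stated. Embryos injected with a control RNA are mentioned in the labels, but no such array was analysed here, nor one with geminin and no Dex, nor one with Dex and no NgnrGR.

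Values were taken as log2(intensity + 5.54), the added value being the 10th percentile of the whole table, so that log2 differences understate the change of dim probe sets. Because the array medians differed by more than the limit of 0.2 set in advance, values were quantile normalized between arrays. Probe sets with a mean log2 value at or above the 25th percentile, 4.24, were tested, 11618 of 15491. limma 3.58.1 in R 4.3.3 fitted 1 coefficient per group over all 6 arrays with lmFit and eBayes with a variance trend. Each of 3 contrasts was adjusted by the Benjamini-Hochberg method over the probe sets tested, with a threshold of 0.05. Adjusted p values of genes throughout are limma's with the replicate number as a block unless stated, and those of gene lists are camera's without it unless stated. Residual degrees of freedom were 3 without the block and 2 with it, and the fitted prior added 2.79 and 7.17. Means and SDs of intensity are of the deposited values, and log2 differences and SEs are of the normalized ones. Figures were drawn with matplotlib 3.10.9.

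The planned design had no replicate block, and the block was set down as an alternative to it. Whether equal numbers pair the arrays was checked from the correlation of their deviations from the group means. These were 0.862 between the no Dex and Dex groups, 0.805 between Dex and geminin plus Dex, and 0.807 between no Dex and geminin plus Dex, and the first principal component separated the numbers. With 2 arrays per group each of these 3 correlations is 1 value, since the deviations of both arrays mirror each other. The numbers were treated as pairing the arrays on this ground. It comes from the data alone, since the labels do not say that a number marks a clutch, batch or day. The block decides every call of a probe set, so both results are given.

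Probe sets were named from the platform annotation, with symbols updated through gene identifiers found in a RefSeq gene table of assembly Xenopus_laevis_v10.1. Of 15491 probe sets 9304 had 1 symbol, of which 9227 were found in that table and 2 changed, 195 had several symbols and stayed unnamed, and 5992 had none here. For each contrast the named genes were the 10 probe sets that rose most and the 10 that fell most among those past the threshold with the block, with 1 symbol and the same direction in both replicate sets. To these were added list members that passed, up to 4 members of a list in which none did, all measured proneural members and the probe sets of both injected RNAs. Values given for probe sets that disagree with a named one were chosen after they were seen.

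The 18 gene lists, written from textbook knowledge, covered the proneural cascade, neuronal differentiation, the Notch pathway, neural progenitors, epidermis, multiciliated cells, ionocytes with secretory and cement gland cells, mesoderm and endoderm, neural crest and placodes, BMP and Id genes, replication licensing, mitosis, the p53 and damage response, the glucocorticoid response, immediate early and stress genes, Polycomb with Trithorax and SWI/SNF, maternal and pluripotency genes, and ribosomal proteins. Each symbol was represented by its brightest probe set. Lists were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 18 lists of a contrast, with an estimated correlation and with fry as alternatives. The fry test asks whether the genes of a list move one way on balance and makes no comparison with other genes. Members were also adjusted over the list alone with the block.

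The fits were tested on simulated data, 20 draws with 200 of 11618 probe sets changed. With each probe set's own moderated variance, the blocked fit recovered 60.5% of 2-fold changes for Dex against no Dex, 58.5% for geminin plus Dex against Dex and 59.5% for geminin plus Dex against no Dex, but 8.51%, 8.40% and 10.1% of its calls were false, above the nominal 5%. A second noise model, with variances drawn from the fitted prior, was added after that result was seen, and the fit itself was left as it was. With it the blocked fit of Dex against no Dex recovered 1.8% of changes of 1.5-fold, 25.1% of 2-fold, 94.5% of 4-fold and 100% of 8-fold, and 4.82% of its calls were false. For geminin plus Dex against Dex it recovered 1.9%, 21.9%, 93% and 99.6%, with 4.80% false, and for geminin plus Dex against no Dex 1.7%, 22.5%, 93.7% and 99.6%, with 4.90% false. Which model is closer to these arrays was not tested, so the share of false calls with the block can be as high as in the first. Without the block, recovery was at most 2.5% at 8-fold in any of these simulations, since the difference between replicate sets then counts as noise.

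Alternatives tried were the replicate block, values as deposited, median centring, no filter, a filter at the 50th percentile, a pseudocount at the 25th percentile (12.96) or of 1, a floor in place of a pseudocount, a fit without the variance trend or with a robust one, a test against a fold of 1.5, only the 4 arrays compared, each array left out in turn, choice and measurement in separate replicate sets, and for lists all probe sets of a member. Random lists were matched on mean expression in 20 bins, 10000 per value. Overlaps of calls between comparisons that share arrays were set beside lists of the same sizes, taken by lowest p, in 100 data sets simulated without any effect, a test added after the overlaps were seen. Groups of 2 are too small for counting other splits of the samples or for an outlier test.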

Results

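Transcript levels were measured on 6 Affymetrix Xenopus laevis arrays, 1 per sample, from animal cap explants, the upper part of the blastula that forms ectoderm when cultured alone. All embryos had received 10 pg of RNA for NgnrGR, in which the neuronal determination factor Ngnr1 is joined to a glucocorticoid receptor domain that holds it inactive until dexamethasone (Dex) is added. Of the 6 arrays, 2 came from explants without Dex, 2 from explants with Dex, and 2 from explants with Dex whose embryos had also received 100 pg of RNA for geminin, a protein that binds the replication licensing factor Cdt1 and also chromatin regulators. The explants were treated with cycloheximide, which blocks protein synthesis, before Dex, and were collected after 2.5 h. Median intensity per array lay between 36.6 and 58.0 over 15491 probe sets. Arrays with the same replicate number resembled each other more than arrays of the same group did. Correlations of log2 values were 0.893 to 0.978 within a number and 0.827 to 0.869 within a group. The first principal component, with 60.2% of the variance, separated replicate 1 from replicate 2, and the second, with 26.98%, separated the geminin arrays from the others. The number of arrays limits the precision of every value. The labels did not say that the replicates came from separate clutches or cultures, so p-values measure only the spread between these samples, which can be technical. Below, "rose" and "fell" are used only of probe sets past the threshold in the limma fit with the replicate number as a block, and "replicate set" means the 3 arrays of 1 number. The endings .L and .S name the 2 copies of a gene in this allotetraploid frog.

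The first comparison, Dex against no Dex, addressed which transcripts responded to active Ngnr1. Of 16 tested members of the proneural list, 2 transcription factors, neurod4.L and ebf2.L, rose. Intensity of neurod4.L, a basic helix-loop-helix neuronal differentiation factor, was 32.6 ± 19.9 without Dex and 318 ± 350 with it (SD, n = 2 each), a log2 difference of 2.62 ± 0.39 (SE, adjusted p = 0.0322). The COE family factor ebf2.L went from 76.4 ± 16.9 to 377 ± 94.1, a log2 difference of 2.28 ± 0.35 (adjusted p = 0.0344). The zinc finger repressor snai1.S, known from neural crest and mesoderm, went from 13.4 ± 3.36 to 176 ± 48.0, with a log2 difference of 3.28 ± 0.33 (adjusted p = 0.00773). Of 27 Notch pathway members 5 fell, of 31 BMP pathway and Id members 3 fell, and cyp26a1.S, which encodes a retinoic acid-degrading enzyme, fell. With the block, the call of snai1.S held without each array in turn and under every other alternative it was tested with. That of neurod4.L was lost without the Dex array (adjusted p = 0.227) or the no Dex array (0.167) of replicate 2. That of ebf2.L was lost without the no Dex array of replicate 2 (0.285) or the Dex array of replicate 1 (0.134) or 2 (0.155). The calls of neurod4.L and ebf2.L also ended with the values as deposited (0.0813 and 0.129), no variance trend (0.116 and 0.137), and a robust variance (0.0876 and 0.0947). So they did with a pseudocount of 1 (0.0522 and 0.0730), a filter at the 50th percentile (0.0501 and 0.0534) and a test against a fold of 1.5 (0.122 and 0.161). That of ebf2.L ended with a floor too (0.0656).

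The other genes with 1 symbol that rose were the zinc finger repressor zbtb18.L at 3.16 on the log2 scale, the selenoprotein selenom.L at 2.77, eps8l3.S at 2.48, the lipid droplet gene cidec.L at 2.06 and spag6.L, a component of motile cilia, at 1.71. Without Dex zbtb18.L and eps8l3.S lay below the 25th percentile of all values, so their sizes hang on the value added before the log. They were 2.66 and 1.98 with a pseudocount at the 25th percentile, and 3.63 and 3.01 with one of 1. With the block, the call of selenom.L held likewise. Without the no Dex array of replicate 2 those of zbtb18.L (adjusted p = 0.158), eps8l3.S (0.134), cidec.L (0.134) and spag6.L (0.422) were lost. Without the Dex array of replicate 1 all 4 were lost too (0.147, 0.164, 0.0775 and 0.247). Without the Dex array of replicate 2 zbtb18.L (0.158), eps8l3.S (0.0762) and spag6.L (0.23) lost it, and without the no Dex array of replicate 1 spag6.L did (0.0514). The calls of zbtb18.L and spag6.L also ended with the values as deposited (0.118 and 0.0941), no variance trend (0.148 and 0.0760), a pseudocount of 1 (0.0793 and 0.0571) and a floor (0.0702 and 0.0552). That of zbtb18.L ended with a robust variance (0.277). That of cidec.L ended with no variance trend (0.0583) and that of eps8l3.S with a pseudocount of 1 (0.0505). All 4 ended against a fold of 1.5 (0.0725 to 0.279). Among the genes that fell, the notochord homeobox gene not.L had a log2 difference of -3.64 ± 0.40, cyp26a1.S -3.43 ± 0.41 and the anterior homeobox gene hesx1.L -2.80 ± 0.26. The Krüppel-like factor klf2.S was at -2.69, the kinase gene sgk1.L at -2.36 and ventx1.1.L at -2.45, although a second, brighter ventx1.1.L probe set was at -0.23 and passed no test. The same direction in both replicate sets was a condition for naming a gene as most changed, so that agreement is no added evidence.

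**Figure D1:**
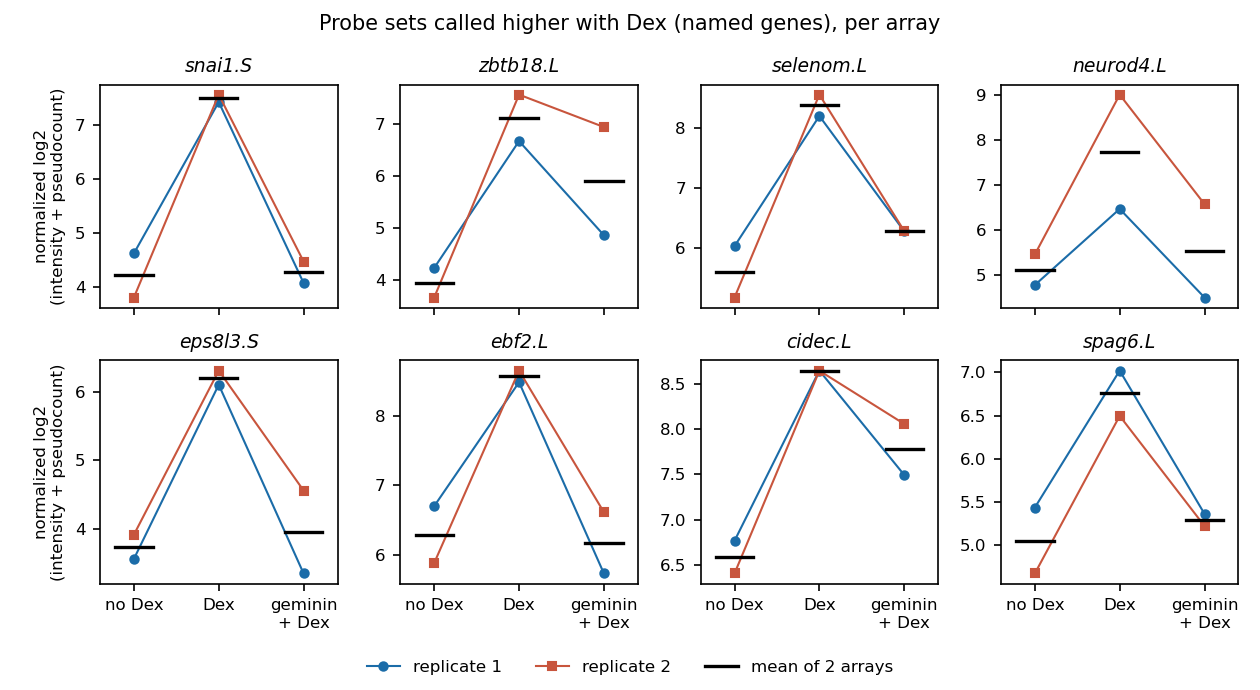
Normalized log2 values (vertical axis, log2 of intensity plus pseudocount, a separate range per panel) of the 8 named genes that rose with Dex, for each array of the no Dex, Dex and geminin plus Dex groups; lines join arrays of 1 replicate number and black bars are means of 2 arrays. All 8 means were lower with geminin than with Dex alone, and the means of zbtb18.L and cidec.L lay above those without Dex by 1.95 and 1.19, with 0.63 and 3.27 for zbtb18.L in replicate sets 1 and 2.

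The proneural list held 16 tested members, of which 15 had a higher mean with Dex, and the median log2 difference was 0.93. Only neurod4.L and ebf2.L rose over all probe sets tested, while 10 were higher and 1 lower when adjusted over the list alone. The members that did not pass over all probe sets were ebf2.S at 2.42 (adjusted p = 0.0969), neurod1.L at 2.19 (adjusted p = 0.0701), myt1.S at 1.69, cbfa2t2.S at 1.45, the Notch ligand dll1.L at 1.11, cbfa2t2.L at 0.98 and insm1.L at 0.87. Below these lay nhlh1.S at 0.72, gadd45g.S at 0.40, tubb2b.S at 0.31, tlx3.S at 0.23, sox4.L at 0.17, gadd45g.L at 0.04 and prdm1.S at -1.38. Against all other genes the list was higher (camera, adjusted p = 1.47e-14), but not with the correlation between genes taken from the data (adjusted p = 0.179 with an estimated correlation). No list passed in any of the 3 comparisons with an estimated correlation, with the block or without it.

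Of the 27 tested Notch pathway members, 5 fell, all of them repressors of the Hairy and Enhancer of split type: hes1.S at -2.65, hes7.2.L at -2.29, esr-5.L at -1.75, hes1.L at -1.70 and hes4.L at -1.16. The ligand dlc.L was at 1.65 (adjusted p = 0.0505), and 2 members were higher and 7 lower when adjusted over the list alone. The list was lower (adjusted p = 0.000576, and adjusted p = 0.306 with an estimated correlation), with a mean of -0.32 and a median of -0.01 that turned to 0.02 with median centring. With the block its call (camera, adjusted p = 0.00728) ended with a filter at the 50th percentile (0.141). It also ended there without the Dex array of replicate 2 and without the no Dex array of replicate 1. Of 31 BMP pathway and Id members, 25 had a lower mean, the median was -0.47, and msx1.L at -2.57, ventx2.1.L at -2.38 and ventx2.1.S at -2.16 fell; 6 were lower when adjusted over the list alone. The list was lower as a whole (adjusted p = 5.54e-14, and adjusted p = 0.101 with an estimated correlation). Genes that glucocorticoid hormones induce in other vertebrate cells were also lower as a list (median -0.20 over 16 members, adjusted p = 1.50e-06, and adjusted p = 0.173 with an estimated correlation). Of these sgk1.L fell and 5 were lower when adjusted over the list alone, while tsc22d3.L at 0.29 and per1.L at 0.17 did not pass. No array had Dex without NgnrGR, so the hormone's own action was not measured apart from that of Ngnr1.

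Smaller shifts of whole lists passed the same test. Epidermal genes had a median of -0.16 over 20 members with none that rose or fell (adjusted p = 0.00256, and adjusted p = 0.382 with an estimated correlation), and 1 was lower when adjusted over the list alone. Mitotic genes had a median of -0.11, with 37 of 48 lower (adjusted p = 0.00837), and ribosomal protein genes one of 0.10, with 63 of 73 higher (adjusted p = 0.000545); both had adjusted p = 0.382 with an estimated correlation, and no member of either passed over all probe sets or over the list alone. Immediate early and stress genes had a median of -0.14 over 32 members (adjusted p = 0.0356, and adjusted p = 0.403 with an estimated correlation), and klf2.S alone fell, over all probe sets and over the list alone. Mesoderm and endoderm markers had a median of -0.19 over 27 members, with not.L and the endodermal factor sox17b.1.S, at -2.0036, the ones that fell (adjusted p = 0.0188, but 0.0629 with the replicate block, and adjusted p = 0.382 with an estimated correlation). When adjusted over the list alone 1 of them was higher and 2 lower. Without the Dex array of replicate 2 all 5 of these calls ended, at adjusted p of 0.914 for epidermis, 0.771 for mitosis, 0.418 for ribosomal proteins, 0.914 for stress and 0.483 for mesoderm and endoderm. Without the no Dex array of replicate 1 those for mitosis (0.838), ribosomal proteins (0.719), stress (0.838) and mesoderm and endoderm (0.0556) ended, and without that of replicate 2 those for epidermis (0.173) and mesoderm and endoderm (0.230). The call for stress genes also ended with median centring (0.0501) and with no filter (0.0664).

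The other 9 lists did not pass, with adjusted p from 0.102 to 0.953. Structural genes of neurons had a median of -0.03 over 20 members, neural progenitor genes -0.07 over 20, and neural crest and placode genes -0.12 over 16, among which snai1.S rose and msx1.L fell. Multiciliated cell genes had a median of -0.06 and a mean of 0.01, with spag6.L the 1 member that rose. Genes of ionocytes and secretory and cement gland cells had a median of 0.06 and a mean of -0.04, with a test direction of higher, and the median was -0.0039 with the values as deposited. Medians were 0.02 for replication licensing, which was -0.05 with the values as deposited, 0.16 for the p53 and damage response, -0.03 for Polycomb, Trithorax and SWI/SNF components and -0.12 for maternal and pluripotency genes. For structural neuronal genes the test direction was higher without the block and lower with it, and the median was 0.0091 with median centring. Maternal genes passed without the Dex array of replicate 1 (0.00419), without the no Dex array of replicate 2 (0.0122) and with all probe sets of each member (0.0176), and damage genes without the no Dex array of replicate 2 (0.00331) and with all probe sets (0.0356). Crest and placode genes passed without the geminin array of replicate 2 (0.0368) and with a filter at the 50th percentile (0.00844), as did multiciliated genes with that filter (0.0298). Adjusted over the list alone, 1 progenitor gene was higher and 2 lower, 2 crest and placode genes were higher and 2 lower, 1 multiciliated gene was higher and 1 lower, 1 secretory gene was lower, 1 damage gene was higher, and 1 maternal gene was higher and 1 lower.

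With the replicate block limma called 35 of 11618 probe sets, 11 higher and 24 lower. At an unadjusted p under 0.05 were 306 higher and 380 lower, where chance gives 580.9 in all. Without the block limma called 0, with 123 at an unadjusted p under 0.05. The blocked count was 11 without the no Dex array of replicate 2, 19 without the Dex array of replicate 2, 70 without the no Dex array of replicate 1, and 295 and 187 without the geminin array of replicate 1 and of replicate 2. Of the 24 genes called here among all those examined by name, 17, 13 and 4 lost the call without the first 3 of these arrays, 10 without the Dex array of replicate 1, and none without a geminin array. With the values as deposited 6 lost it, namely neurod4.L, ebf2.L, zbtb18.L, spag6.L, hes4.L and ventx1.1.L. The number was 12 with no variance trend, 5 with a robust variance, 10 with a pseudocount of 1, 6 with a floor, 16 against a fold of 1.5, and 3 of 16 with a filter at the 50th percentile. With the block, snai1.S, selenom.L, not.L, hesx1.L, sgk1.L and ventx2.1.L kept it under every alternative each was tested with. The split was 18 higher and 25 lower with median centring, and 7 higher and 18 lower with the values as deposited. Differences of the 2 replicate sets correlated at r = 0.338 across probe sets, which are not independent replicates.

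The second comparison, geminin plus Dex against Dex, addressed whether geminin suppresses the response to Ngnr1. The injected RNA was visible in the geminin probe set gmnn.L, at 290 ± 68.5 with Dex and 2650 ± 700 with geminin added (SD, n = 2 each), a log2 difference of 3.23 ± 0.16 (adjusted p = 3.26e-05). The other copy, gmnn.S, was at 477 ± 192 and 606 ± 433 and did not pass (adjusted p = 0.376). The neurog2 probe sets, which stand for the injected Ngnr1, had mean intensities of 5.95 to 34.0 in every group, and they can lie outside the injected construct and so checked nothing. Of the 11 probe sets that rose with Dex, 9 fell with geminin. Of 20 epidermal genes 11 fell and 1 rose, of 20 neural progenitor genes 9 fell and 1 rose, and of 31 BMP pathway and Id genes 10 fell and 3 rose. Of the named genes, hsp70.L, which encodes a heat-shock protein, fell most, at a log2 difference of -5.55 ± 0.50. Its intensity with geminin, 8.21, lay near the lowest values, and the difference was -4.90 with a pseudocount at the 25th percentile and -6.24 with one of 1.

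All 11 probe sets that rose with Dex had a lower mean with geminin, and 9 of them fell. Intensity of snai1.S fell from 176 ± 48.0 to 14.0 ± 7.54 (log2 difference -3.22 ± 0.33), that of ebf2.L from 377 ± 94.1 to 74.5 ± 53.2 (-2.40 ± 0.35), and that of selenom.L from 331 ± 112 to 71.7 ± 22.5 (-2.09 ± 0.29). Also eps8l3.S at -2.27, neurod4.L at -2.20, spag6.L at -1.47 and cidec.L at -0.87 fell, while zbtb18.L at -1.21 did not pass (adjusted p = 0.153). Calls were lost without the Dex array of replicate 1 for eps8l3.S (0.0881), spag6.L (0.133) and cidec.L (0.314), without that of replicate 2 for neurod4.L (0.0601) and cidec.L (0.143), and without the geminin array of replicate 1 for cidec.L (0.249). The call of cidec.L also ended with the values as deposited (0.0689), no filter (0.0517), no variance trend (0.0898), a pseudocount of 1 (0.0597) and a floor (0.0583). Against a fold of 1.5 those of neurod4.L (0.0568), spag6.L (0.110) and cidec.L ended. The difference of zbtb18.L was -0.26 without the geminin array of replicate 1 (0.739), and it passed at -2.17 without that of replicate 2 (0.00504) and without the no Dex array of replicate 1 (0.0378) or 2 (0.0334). Because both comparisons use the same Dex arrays, chance alone pushes them apart. In 100 simulated data sets with induction and no geminin effect, 69.8% of the induced probe sets had a lower mean and 0.191% were called lower; there the noisy observed differences served as true ones, so that 261 were called induced on average. Independent lists of these sizes would share 0.878. In data simulated without any effect, lists of these sizes taken by lowest p shared 7.40 ± 1.38 (SD, 100 simulations) of 11, so part or all of the count of 9 can come from the shared Dex arrays. Without the Dex array of replicate 1 the count was 4 of 6 induced probe sets, without the no Dex array of replicate 2 it was 4 of 4, and without that of replicate 1 it was 34 of 38. Without the geminin array of replicate 1 it was 52 of 125, a lower share, and without that of replicate 2 it was 59 of 72. Without the block it was 0, since limma then called no induced probe set. When the 100 probe sets with the largest Dex difference were chosen in 1 replicate set and measured in the other, which shares no array, 91 and 76 of 100 were lower with geminin, with median log2 differences of -0.98 and -1.27. In the measuring set 72 and 89 of them were higher with Dex, with medians of 0.62 and 0.76. Both falls were larger than these Dex differences, so they need not be loss of a Dex response alone.

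In the proneural list 15 of 16 members had a lower mean with geminin, with a median of -1.22, and 9 fell (12 lower when adjusted over the list alone). They were ebf2.S at -3.32, neurod1.L at -2.57, ebf2.L at -2.40, neurod4.L at -2.20, cbfa2t2.S at -2.07, cbfa2t2.L at -1.74, myt1.S at -1.69, prdm1.S at -1.55 and gadd45g.S at -0.82. The members that did not pass ran from dll1.L and insm1.L, both at -0.89, to sox4.L at 0.49. The list was lower than other genes (adjusted p = 8.72e-09, and adjusted p = 0.170 with an estimated correlation). The planned share of the Dex response left with geminin had a median of -0.114 over this list, at -1.01 in replicate set 1 and 0.241 in replicate set 2. It measures no retention, since of the members it divides by only neurod4.L and ebf2.L rose with Dex. Over the 11 called probe sets it was 0.244. Selection used the Dex and no Dex arrays, and both enter the share, so the direction of the bias is not known. It was 0.0722 without the no Dex array of replicate 2 and -0.302 without the geminin array of replicate 2. Its sign was not settled.

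Epidermal genes had the lowest median of the 18 lists, -1.80 over 20 members, of which 11 fell and 1 rose (14 lower and 2 higher when adjusted over the list alone). Intensity of the homeobox gene dlx3.S went from 251 ± 95.8 to 9.52 ± 7.45, a log2 difference of -4.12 ± 0.38, and that of gata2.L from 208 ± 35.6 to 8.64 ± 7.15, a log2 difference of -4.00 ± 0.33. With geminin both lay below the 25th percentile of all values, 12.96, and no detection call was at hand, so these sizes hang on the value added before the log. They were -3.54 for dlx3.S and -3.40 for gata2.L with a pseudocount at the 25th percentile, and -4.69 and -4.62 with one of 1. A second, dimmer gata2.L probe set was at -0.41 and did not pass. Also dlx3.L at -3.08, dlx5.L at -2.89, tfap2a.L at -2.51, the grainyhead factor grhl3.L at -1.92 and E-cadherin, cdh1.S, at -1.97 fell, whereas krt19.L rose by 0.75. With geminin cdh1.S was as dim, and its difference was -1.42 with a pseudocount at the 25th percentile and -2.84 with one of 1. The list was lower (adjusted p = 5.74e-08, and adjusted p = 0.170 with an estimated correlation).

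Neural progenitor genes fell as well, 9 of 20, with 1 that rose (10 lower and 1 higher when adjusted over the list alone) and a median of -0.54. The anterior homeobox gene otx2.L was at -3.00, irx1.L at -2.13 and sox2.L at -1.29, and zic2.L rose by 1.02. With geminin otx2.L lay below the 25th percentile of all values. Its difference was -2.39 with a pseudocount at the 25th percentile and -3.78 with one of 1. In the Notch list 9 of 27 fell, with a median of -0.85, led by dtx4.L at -2.30, hes5.2.L at -2.12 and hes2.L at -1.86, and including the ligand dlc.L at -1.45 (16 lower and 1 higher when adjusted over the list alone). In the BMP and Id list 10 of 31 fell and 3 rose, with a median of -0.34 (11 lower and 3 higher when adjusted over the list alone). The secreted feedback inhibitor szl.L was at -4.41 ± 0.37, bambi.L at -2.01 and id2.S at -1.71, while bmp2.L rose by 1.34 and the receptor acvr1.L by 1.32. All 3 lists passed, at adjusted p of 3.18e-05 for progenitors, 5.89e-07 for Notch and 4.11e-05 for BMP, each with adjusted p = 0.170 with an estimated correlation. Structural neuronal genes had a median of -0.10, with celf3.S at -2.63, prph.L at -1.96, elavl3.L at -1.60 and dpysl2.L at -1.41 lower and nefl.L 1.48 higher (5 lower and 1 higher when adjusted over the list alone). With geminin prph.L and elavl3.L were dim too, at -1.50 and -1.19 with a pseudocount at the 25th percentile. The call of the structural neuronal list (adjusted p = 0.0143, and adjusted p = 0.170 with an estimated correlation) ended with the block (0.0552), without the geminin array of replicate 2 (0.0943) and without the no Dex array of replicate 2 (0.0521).

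Ribosomal protein genes had a median of -0.34, with 59 of 73 lower and 16 that fell, such as rps21.S at -1.08 and rps6.L at -1.05 (18 lower and 1 higher when adjusted over the list alone; adjusted p = 6.90e-08, and adjusted p = 0.337 with an estimated correlation). The remaining 11 lists did not pass, with adjusted p from 0.134 to 0.923. In the immediate early and stress list 9 of 32 fell and 3 rose (10 lower and 5 higher when adjusted over the list alone), including hsp70.L, hsp90ab1.S at -1.40 and myc.S, which rose by 1.32. This list passed without the geminin array of replicate 1 (0.00244), without the Dex array of replicate 2 (0.0332) and with a filter at the 50th percentile (0.00363). Among ionocyte and gland genes foxi1.L at -3.47, ubp1.L at -3.06, foxa1.S at -1.08 and ag1.L at -1.06 fell, though the median was 0.16, with a mean of -0.45 and a test direction of lower. In the multiciliated list spag6.L, ccno.L at -0.89 and tubb4b.L at -0.82 fell, with a median of -0.09, and the list passed without the geminin array of replicate 1 (0.0333). In the p53 and damage list 4 fell, led by ccng1.L at -2.87, and chek1.S rose by 1.01, with a median of -0.32, and the list passed with that filter (0.0101).

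Mesoderm and endoderm markers had 3 that fell, led by a2m.S at -2.93, and 3 that rose, led by not.L at 1.58, with a median of 0.01, a mean of -0.10 and a test direction of lower; the median was -0.07 with the values as deposited. Neural crest and placode genes had a median of 0.37, with snai1.S and pax3.L, at -1.76, lower and ets1.S, myc.S and myc.L higher. Of 56 replication licensing genes 6 fell and 4 rose (median -0.06), and of 48 mitotic genes 5 fell and 6 rose (median 0.21). Of the glucocorticoid-responsive genes 2 fell and 3 rose, with a median of 0.0033 that was -0.04 with the values as deposited and a mean of -0.01, and of the maternal and pluripotency genes 4 fell and 5 rose, with a median of 0.12. In the Polycomb, Trithorax and SWI/SNF list cbx1.S alone fell, at -0.95, with a median of 0.03 that was -0.04 with the values as deposited. Adjusted over the list alone, the counts lower and higher were 4 and 0 for ionocytes and glands, 4 and 0 for multiciliated cells, 5 and 1 for damage, 3 and 4 for mesoderm and endoderm, and 2 and 5 for crest and placode. They were 7 and 5 for replication, 7 and 7 for mitosis, 4 and 3 for glucocorticoid response, 5 and 7 for maternal genes and 1 and 0 for Polycomb, Trithorax and SWI/SNF.

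**Figure D2:**
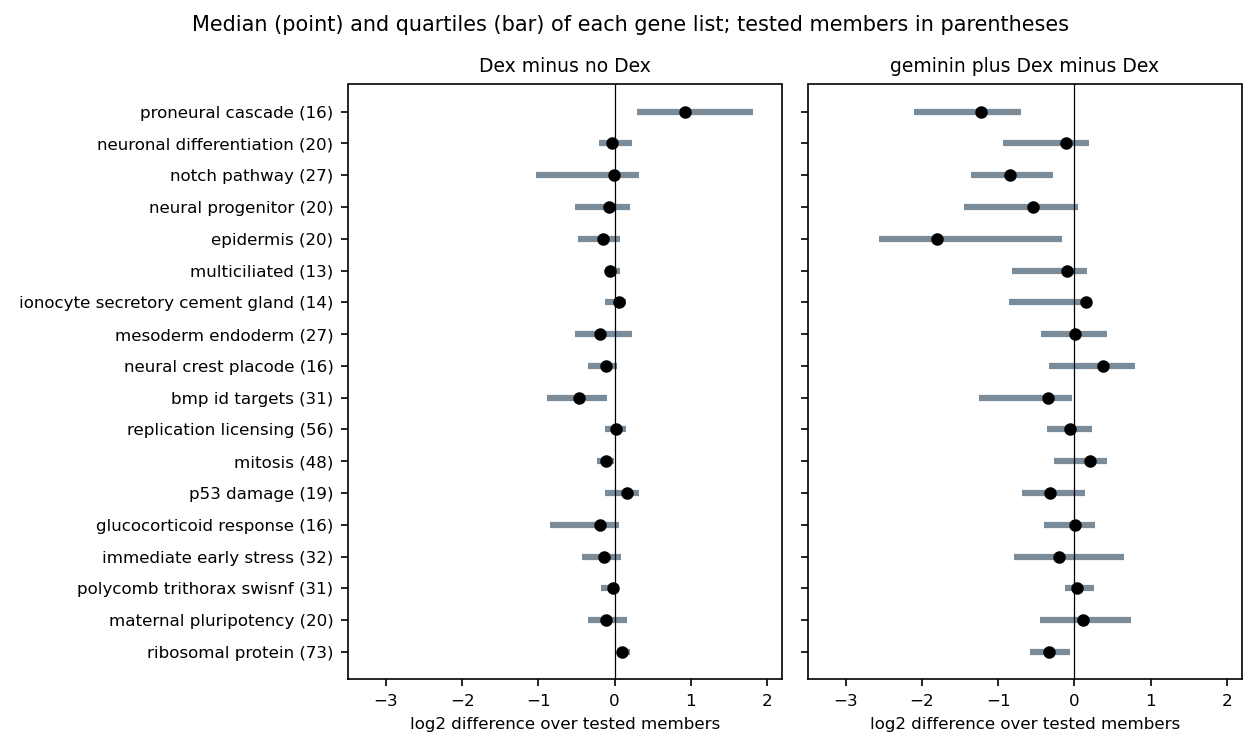
Median (point) and quartiles (bar) of the log2 difference over the tested members of each of the 18 gene lists, for Dex minus no Dex (left) and geminin plus Dex minus Dex (right), with the number of tested members in parentheses. The proneural list has medians of 0.93 and -1.22, and the epidermal list medians of -0.16 and -1.80.

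Besides gmnn.L, the genes that rose most with geminin were LOC398162 at 3.21, a cirbp.L probe set at 2.75, btg4.L at 2.70, the tRNA splicing gene tsen54.L at 2.29, the gamma-tubulin gene tubg1.L at 2.14, cldn5.S at 2.06, dkc1.L at 2.05, fbxo43.L at 2.04 and zfp36l2.1.S at 2.02. The probe sets of cirbp, which encodes a cold-inducible RNA-binding protein, disagreed: a much brighter cirbp.L probe set was at -0.24, and those of cirbp.S were at -0.43 and 1.55. Besides those above, ptgds-b at -5.07, hspbp1.L at -4.44 and the creatine synthesis gene gatm.L at -3.38 were among the genes that fell most. With the block limma called 1444 probe sets, 517 higher and 927 lower, and 3165 had an unadjusted p under 0.05, 1545 higher and 1620 lower. With the values as deposited 317 were called higher and 812 lower. Without the block limma called 0, with 847 at an unadjusted p under 0.05. The blocked count was 179 without the Dex array of replicate 1 and 940 without that of replicate 2, and of 174 and 175 named genes with a call 123 and 46 lost it. With the values as deposited 17 of 174 lost it, with no variance trend 43 of 175, and against a fold of 1.5 119 of 175.

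The third comparison, geminin plus Dex against no Dex, gave what remained of the response with geminin, together with any action of geminin itself, since no array had geminin without Dex. Of the 11 probe sets that rose with Dex, 4 were still higher, against 0.530 for independent lists and 6.71 ± 1.44 for lists of these sizes in data simulated without any effect, since both comparisons share the no Dex arrays. Of these, zbtb18.L was at 1.95 ± 0.50 (adjusted p = 0.0325), with 0.63 in replicate set 1 and 3.27 in replicate set 2. Its call was lost without the geminin array (0.99, adjusted p = 0.138) or the no Dex array (0.94, adjusted p = 0.289) of replicate 2, and with the values as deposited (0.0580), no variance trend (0.0644), a robust variance (0.103) or a test against a fold of 1.5 (0.197). It was at 2.92 without the no Dex array of replicate 1 (0.00326). Of cidec.L, at 1.19 ± 0.24 (adjusted p = 0.0140), with 0.73 and 1.65 in the replicate sets, the call was lost without the no Dex array of replicate 2 (0.87, adjusted p = 0.189) and against a fold of 1.5 (0.273). In the proneural list 1 member fell, prdm1.S at -2.93, which was also the 1 member lower when adjusted over the list alone. The list had a median of -0.25, or -0.42 with the values as deposited, and did not pass (adjusted p = 0.108). It passed as lower without the geminin array of replicate 2 (0.000567), with all probe sets of each member (0.0110) and with a filter at the 50th percentile (0.0302). All 24 probe sets that fell with Dex also fell in this comparison, against 2.07 for independent lists and 14.9 ± 2.54 for lists of these sizes simulated without any effect. Part of the overlap can come from the shared no Dex arrays. Of these 24, 7 fell further from Dex to geminin plus Dex (1.91 for independent lists and 0.22 simulated), and not.L and sgk1.L rose (1.07 and 12.7).

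Epidermal genes again had the lowest median, -1.90, with 13 of 20 that fell and 1 that rose (14 lower and 1 higher when adjusted over the list alone), including gata2.L at -5.19 and dlx3.S at -4.86, or -4.56 and -4.27 with a pseudocount at the 25th percentile, since both were near the lowest values with geminin. In the BMP and Id list the median was -0.96, and 15 of 31 fell and 1 rose, led by szl.L at -5.31 (17 lower and 3 higher when adjusted over the list alone). The Notch list had a median of -0.96, with 13 of 27 that fell, led by hes1.S at -3.45 (15 lower and 1 higher when adjusted over the list alone). Of the neural progenitor genes 10 of 20 fell and 1 rose, including otx2.L at -4.19, which was as dim with geminin, (11 lower and 1 higher when adjusted over the list alone). These 4 lists passed, at adjusted p of 2.21e-09, 5.25e-12, 8.92e-10 and 4.47e-06, and had adjusted p = 0.210, 0.103, 0.103 and 0.103 with an estimated correlation. The structural neuronal (median -0.13, adjusted p = 0.0164), glucocorticoid-responsive (-0.46, 0.00921), stress (-0.46, 0.0142) and ribosomal protein (-0.20, 0.000460) lists also passed as lower, at adjusted p = 0.220, 0.232, 0.546 and 0.546 with an estimated correlation. In these, 4, 7, 11 and 9 members fell and 1, 1, 2 and 1 rose, including celf3.S at -2.52, tsc22d3.S at -2.03, hsp70.L and rps6.L at -0.93 among those that fell. With the values as deposited the ribosomal median was -0.40. Adjusted over the list alone, 5, 8, 15 and 9 members of these 4 lists were lower and 1, 1, 6 and 1 higher. Each of these 4 calls ended without 1 array or another: without the geminin array of replicate 2 for neuronal (0.117), glucocorticoid (0.179) and stress genes (0.454), without that of replicate 1 for ribosomal genes (0.545), without the no Dex array of replicate 1 for neuronal (0.0626) and stress genes (0.150), and without that of replicate 2 for neuronal (0.134) and ribosomal genes (0.124).

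The other 9 lists of this comparison did not pass, with adjusted p from 0.0851 to 0.849. Mesoderm and endoderm markers had a median of -0.01, with 5 that fell, led by a2m.S at -2.84, and 1 that rose, vegt.L at 1.23, and they passed without the geminin array of replicate 1 (0.0115), with no filter (0.0331) and with a filter at the 50th percentile (0.00115). Multiciliated genes had a median of -0.02, with 3 that fell, led by the ciliogenic factor rfx2.S at -1.83, and passed without the geminin array of replicate 1 (0.0445) and with that filter (0.0108). Ionocyte and gland genes had a median of 0.10 and a mean of -0.49, with 3 that fell, and crest and placode genes a median of 0.24, with 3 that rose and 2 that fell. Replication genes had a median of -0.06, with 6 that rose and 8 that fell, and mitotic genes one of 0.06, with a mean of -0.05, a test direction of lower, 5 that rose and 6 that fell. Damage genes had a median of 0.05 and a mean of -0.23, with 4 that fell, maternal genes a median of 0.21 and a mean of -0.06, with 5 that rose and 4 that fell, and Polycomb, Trithorax and SWI/SNF genes a median of 0.02, with cbx1.S at -0.87 lower. With the values as deposited these medians were -0.19 for replication, -0.11 for mitosis, -0.15 for damage, 0.11 for maternal genes and -0.05 for Polycomb, Trithorax and SWI/SNF. Adjusted over the list alone, the counts lower and higher were 7 and 1 for mesoderm and endoderm, 4 and 0 for multiciliated cells, 3 and 1 for ionocytes and glands, 2 and 4 for crest and placode, 8 and 8 for replication, 6 and 6 for mitosis, 4 and 0 for damage, 4 and 5 for maternal genes and 0 and 0 for Polycomb, Trithorax and SWI/SNF.

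Of the genes that fell most, serpinh1.S, a collagen chaperone, was at -5.19 ± 0.25, hsp70.L at -4.96, ubp1.L at -4.72, cyp26a1.S at -4.70, foxi4.2.L at -4.47, hspbp1.L at -4.36 and klf17.1.S at -4.31. With geminin serpinh1.S, hsp70.L and ubp1.L lay below the 25th percentile of all values. Their sizes and order hang on the added value, with -4.54, -4.32 and -4.20 at the larger pseudocount. The size of cyp26a1.S, at 15.4 with geminin, hung on it too, with -4.03 at the larger pseudocount and -5.66 with one of 1. A group mean below that percentile was part of 2 of 24, 19 of 172 and 24 of 175 called genes examined by name in the 3 comparisons. The last 2 totals are slightly smaller than the 175 and 178 named genes used to count lost calls. The genes that rose most were cirbp.L at 2.98, gmnn.L at 2.76, LOC398162 at 2.60, tsen54.L at 2.52, cldn5.L at 2.09, tubg1.L at 2.09, dkc1.L at 2.01, h2ax.lS at 1.97 and cldn5.S at 1.95. With the block limma called 1564 probe sets, 560 higher and 1004 lower, with 3428 at an unadjusted p under 0.05, of which more were higher (1799) than lower (1629). Without the block limma called 0, with 899 at an unadjusted p under 0.05. The blocked count was 657 without the no Dex array of replicate 1 and 624 without that of replicate 2, and of 177 and 176 named genes with a call 64 and 69 lost it. With the values as deposited 13 of 177 lost it, with no variance trend 35 of 178, and against a fold of 1.5 90 of 178. The median of all probe sets tested was 0.11 with quantile normalization and -0.00142 with the values as deposited, which gave 242 higher and 1078 lower, so log2 differences here are to be read against that shift. The calls of this comparison and of the second overlapped in 718 probe sets that fell and 352 that rose, against 80.1 and 24.9 for independent lists and 302.4 ± 12.0 and 137 ± 9.51 for lists of these sizes simulated without any effect. Part of the overlap can come from the shared geminin arrays.

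Over all probe sets tested, the Dex difference and the geminin difference correlated at r = -0.0948, whereas data simulated without any effect gave -0.4996 ± 0.00744 (SD, 100 simulations) because the Dex arrays are shared. Their covariance was -0.0214 against -0.0333 simulated, a difference of 0.0119. Taking the Dex difference from 1 replicate set and the geminin difference from the other gave r = -0.102 and 0.0973, so no direction held over all probe sets.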

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

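Alternatives combined with the replicate block, and the fit of only the 4 arrays compared with it, were tests chosen after the data were seen, while the block alone, the other alternatives without it and the separate replicate sets were planned. Without the block limma called 0 probe sets in each comparison under every alternative and without each array, with 123, 847 and 899 at an unadjusted p under 0.05. The block, which takes equal numbers as pairs, raised the counts to 35 for Dex, 1444 for geminin plus Dex against Dex and 1564 against no Dex. It raised that of Dex-induced probe sets lower with geminin from 0 to 9. All of these counts fall back to 0 with no replicate block. The 91 and 76 of 100 in separate replicate sets count only the sign of the difference, and depend on no call. Each difference was taken between arrays of the same number, so these counts also treat equal numbers as pairs. Among lists the block ended the calls for mesoderm and endoderm with Dex and for structural neuronal genes with geminin against Dex, and changed no other.

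With the block, the count for Dex was 22 with a filter at the 50th percentile, 11 against a fold of 1.5, 16 with no variance trend and 258 with only the 4 arrays compared, and 11 to 295 without 1 array (11, 19, 70, 187 and 295 where it moved most). For geminin plus Dex against Dex it was 243 against a fold of 1.5 and 179 to 1897 without 1 array (179 and 940 without a Dex array), and against no Dex 402 and 624 to 1932 (657 and 624 without a no Dex array). Dex-induced probe sets lower with geminin numbered 4 of 5 with the stricter filter, 3 of 4 against a fold of 1.5, 15 of 18 with median centring, 5 of 5 with no variance trend, 5 of 7 as deposited, 18 of 20 with a pseudocount at the 25th percentile, 4 of 6 with a pseudocount of 1, and 4 to 59 without 1 array (34 of 38, 52 of 125 and 59 of 72 at the upper end). No call of a named gene turned direction under any alternative with the block, though without a Dex or no Dex array up to 17 of 24, 123 of 174 and 69 of 176 were lost. For the proneural list the retained share ran from -0.478 to 0.208 under the alternatives. Within replicate sets 1 and 2 alone it was -1.01 and 0.241, outside that range. Most members of that list showed no called response to divide by. For the called probe sets the share ran from -0.302 to 0.361 without 1 array. The correlation of both differences was 0.0973 with the Dex difference from replicate set 2 and the geminin difference from replicate set 1.

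Lists past the threshold numbered 9, 7 and 8 in the 3 comparisons, or 8, 6 and 8 with the block, and 0 with an estimated correlation in either fit. With fry they numbered 0, 1 and 5, and 0 in each with the block. Without 1 array they numbered 4 to 10, 6 to 9 and 6 to 9, or 5 to 10, 6 to 9 and 7 to 9 with the block, and with the block and the stricter filter 10 for geminin plus Dex against Dex. The epidermal list with Dex turned direction, with the block and without the Dex array of replicate 2 (adjusted p = 0.173). Why results moved was not tested, also where fewer arrays or probe sets entered a fit. Fewer arrays leave fewer residual degrees of freedom, so a lost call need not mean that a result rests on that array. Without 1 array of a group, the lone sample left was assumed to vary like the others. Probe sets near background hold little signal, and the added pseudocount shrinks their differences.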

Other observations

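The tests of chaperones and of maternal and zygotic gene pairs, with the lists they used, the simulated overlap of 7.40, and the count of arrays with geminin outside the geminin plus Dex group were chosen only after the result was seen.

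Of 16 tested cytosolic heat-shock chaperones and co-chaperones, 9 fell with geminin and none rose in the limma fit with the block, and 11 were lower in both replicate sets. No test of the list against other genes was made. The differences of chordc1.S, fkbp4.S and hspa4.S were positive, at 0.20, 0.22 and 0.40, and bag3.L (0.70 and -0.98) and dnaja1.L (-0.42 and 0.15) went both ways in replicate sets 1 and 2. Besides hsp70.L and hspbp1.L these included the Hsp90 activators ahsa1.L at -2.85 and ahsa1.S at -2.18 and the co-chaperone dnaja4.1.L at -1.93. With Dex alone their median was 0.04 and limma called 0 of the 16. Of 27 chaperones of the endoplasmic reticulum and mitochondria 3 fell, hspa5.S at -1.77, pdia4.L at -1.13 and calr.S at -0.76, and 2 rose, dnajb9.L at 0.99 and creld2.L at 0.91. That list left out the collagen chaperone serpinh1.S of the endoplasmic reticulum, which fell (-3.07), and dnajb14.S of its membrane, which rose (1.33). Of these, serpinh1.S also fell with Dex against no Dex (-2.11).

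In 5 pairs of related genes, of which 1 is mainly maternal and the other mainly zygotic, the maternal member was higher relative to its partner with geminin in both replicate sets. The pairs were chosen after their values were seen, other such pairs were not counted, and no test of the pairs was made. The maternal ccna1, wee2, mcm3 and pou5f3.3 were higher relative to zygotic ccna2, wee1, zmcm3 and pou5f3.1, as was mcm6 relative to mcm6.2. The differences between partners were 4.26 and 2.12 on the log2 scale in replicate sets 1 and 2 for the POU factors, 2.76 and 1.86 for the Wee1 kinases, 2.41 and 2.50 for MCM3, 1.29 and 1.26 for cyclin A and 0.87 and 1.21 for MCM6. The cyclin ccna2.L (-0.07, adjusted p = 0.816), ccna2.S (-0.10, adjusted p = 0.738), mcm6.L (0.07, adjusted p = 0.893, with -0.25 and 0.40 in the replicate sets), mcm6.2.S (-0.90, adjusted p = 0.0928) and a second wee1.S probe set at -0.35 did not pass, while the other members' probe sets did with the block, except a dimmer one of mcm6.2.S.

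All 11 probe sets that rose with Dex had a lower mean with geminin. The count of 9 that fell does not settle this, since the simulations differed. Lists of these sizes, taken by lowest p and not by call, shared 7.40 of 11 without any effect. With induction and no geminin effect, 0.191% of the induced probe sets were called lower, but there noisy differences served as true ones. Selection on the shared Dex arrays was argued against by probe sets chosen in 1 replicate set, which had medians of -0.976 or lower in the other. These differences, too, were taken between arrays of the same number. A general fall of transcripts of that abundance was argued against too, since both medians lay at percentile 0 of 10000 matched random lists. Those lists were matched on mean expression alone, so a fall shared with other regulated genes was not tested and stays open. Epidermal genes, none of them called with Dex, had the lowest median of the 18 lists with geminin, -1.80. More injected RNA or other handling of the geminin explants stays open, with 0 arrays with geminin RNA outside the geminin plus Dex group. A suppression by geminin itself may account for the pattern and remains a hypothesis. Arrays with geminin and no Dex, or with a control RNA, would be needed to test it. Of the 24 probe sets that fell with Dex, 7 fell further with geminin. Independent lists gave 1.91, and lists in data simulated without any effect 0.22. Only 2 rose, against 1.07 and 12.7, so few of the falls with Dex were called reversed. The simulated data held no geminin effect, so their values are no expectation for arrays with many geminin calls.

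For the chaperones, a fall in every compartment stays open. The cytosolic median minus that of the other chaperones was -0.795 and -0.707 in replicate sets 1 and 2, but the lists were written after the values were seen and left out called genes such as serpinh1.S, so this excludes nothing. A difference in temperature or handling between explants could also give this pattern, and it stays open because 0 arrays separate handling from geminin.

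For the gene pairs, 5 of 5 kept their direction in both replicate sets with the values as deposited and with median centring. A factor per array cancels within a pair, so this outcome was fixed and decides nothing about the scaling between arrays, where a distortion that depends on brightness stays open. A slower loss of maternal transcripts in general may still contribute. The maternal and pluripotency list had medians of 0.161 and 0.135 in the 2 replicate sets, but did not pass (adjusted p = 0.714 with the block), which leaves this open.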
